A study of Mus musculus with 4 samples.

How the data were processed

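Gene expression was measured by RNA sequencing in 4 libraries of B16F10 cells, 2 from cells given plain olive oil and 2 from cells given ozonated olive oil, each at 0.01% for 6 h. Per the labels' protocols, RNA was extracted with a phenol-based reagent and libraries were made with a directional kit, which keeps the strand of each transcript. The submitters' processing notes name bcl2fastq, FastQC 0.11.7, HISAT2 2.1.0, SAMtools 1.9, StringTie 1.3.4d, bedtools 2.27.1 and edgeR, with the genome build mm10. The program that assigned reads to genes, its annotation and its strand setting are not given in the sources used here. The strand setting being unstated, reads of overlapping and antisense genes may have been counted together.

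The deposited table holds whole-number read counts per gene, not normalized, for 27179 genes in 4 columns, and each column name matched the label of a single library. Of these genes, 1319 had no symbol, and they held 0.197% to 0.218% of the counts of a library. Treatment of reads that match several places is not given in the sources used here. Values of genes with near-identical copies or many pseudogenes (Hspa1a and Hspa1b, ribosomal protein genes, histone genes, Gapdh and Pgam1 among them) are therefore uncertain. Gene positions were taken from the RefSeq annotation of GRCm38.p6, the assembly that mm10 is based on, by Entrez identifier, for 97.7% of tested genes. Transcript lengths and GC content came from the longest annotated transcript of the same build.

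Total counts were 22539486 and 23377947 in the plain oil libraries and 22766948 and 30038784 in the ozonated oil libraries. The libraries of a group differed by far more than counting noise, with a chi-square per degree of freedom of 39.0 for plain oil and 129 for ozonated oil, so no pair was treated as repeat files of 1 library. This does not show that they came from separate cultures. The common biological coefficient of variation between libraries of a group was 0.230.

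Analyses were run in R 4.3.3. Genes with low counts were removed with filterByExpr of edgeR 4.0.16, which left 12675 genes, and libraries were scaled by the trimmed mean of M-values. The groups were compared with the quasi-likelihood F-test of edgeR with group as the only term, two-sided, with Benjamini-Hochberg adjustment over all genes tested and a threshold of 0.05. Changes are given as log2 of ozonated over plain oil with a standard error taken from the F statistic, and levels as CPM on the scaled library sizes, as mean ± SD with n = 2 per group. Any p-value given for a gene without the word adjusted is an unadjusted value of this edgeR test. With 2 libraries against 2, an exact two-sided permutation test cannot go below p = 0.333, so none was used.

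Gene lists were tested with camera of limma 3.58.1 at a preset inter-gene correlation of 0.01, with Benjamini-Hochberg adjustment over the 29 lists that had at least 3 tested members, out of 32. Estimated correlations of the lists called this way ran from 0.0011 (ferroptosis and iron) to 0.988 (ribosomal proteins). Besides ferroptosis and iron, sterol synthesis (0.0062) alone had an estimate below the preset. Where the estimate is far above the preset, p-values at the preset count genes that vary together as nearly independent. The lists, the tests and the rule for naming genes were fixed before the data were examined. Members were also counted after Benjamini-Hochberg adjustment over the list alone. The rule for naming genes had 3 parts. The first took up to 10 genes per direction with adjusted p below 0.05, a mean of at least 5 CPM and groups that did not overlap, and 0 genes met it. The second took up to 4 members of each list by smallest p. The third took 17 genes whatever their result. Some genes that the rule names are not reported here. Genes named outside this rule are said to have been chosen after their values were seen.

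The alternatives were median-of-ratios scaling, no filter, a filter of 1 CPM in at least 2 libraries, the replicate number as a block, each library left out in turn, the Wald test of DESeq2 1.42.0, a test against a fold change of 1.5, stricter thresholds, camera with an estimated correlation, and fry. After the data were examined, a fit with transcript length and GC trends removed and a fit without the ribosomal RNA precursor gene Rn45s were added, as were 2 gene lists used only in the closing section. With 1 library of a group left out, the lone library was assumed to vary like the other group.

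The tests were tried on counts simulated from the real means and library sizes, in 5 draws of 12675 genes with 200 changed. Each gene kept the spread that edgeR fitted to it, equal in both groups, with no effect of replicate number. The rates below need not hold for the real libraries. The edgeR test recovered 22.2% of genes changed 2-fold and 82.8% of those changed 4-fold, and 9.7% of its calls were false. DESeq2 recovered 36.8% and 84.8%, with 19.7% of its calls false. A 30-gene list shifted by 0.5 on the log2 scale was called in 5 of 5 draws and an unshifted list in 0. Genes were drawn independently, so these draws cannot show how camera behaves on lists whose genes vary together.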

Results

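B16F10 is a mouse melanoma cell line that makes pigment. Its response to ozonated olive oil was compared with its response to plain olive oil after 6 h of culture with either oil at 0.01%. Ozone reacts with the double bonds of unsaturated fatty acids, and the comparison asked which transcripts differed in cells given the ozone-treated oil. Each group held 2 libraries. Plain oil libraries 1 and 2 had 22539486 and 23377947 counts, and ozonated oil libraries 1 and 2 had 22766948 and 30038784. Between 15457 and 16068 genes had at least 1 count in a library. Cells without oil were not analysed here. The labels do not say whether the replicates are separate cultures, so p-values measure only the spread between these samples, which may be technical.

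Across the transcriptome, the genes with the smallest p-values included Slc7a11, the cystine importer, at 3.95-fold the plain oil level, and Myc, a transcription factor of cell growth, at 0.153-fold. Jun, a stress-responsive transcription factor, was at 3.98-fold and Hmox1, the heme-degrading enzyme, at 6.55-fold. On the lower side stood Spsb4 (0.229-fold), Cdca7 (0.228-fold), Igf2bp1 (0.272-fold), which encodes an RNA-binding protein, and Dusp6 (0.157-fold), a phosphatase of ERK. Sap30, Crebrf, Clk4, Eno2, Kif21b and Klf11 were higher by 2.49-fold to 5.00-fold. Of the genes in this paragraph, those outside the fixed lists and rule (Spsb4, Cdca7, Igf2bp1, Sap30, Crebrf, Clk4, Eno2, Kif21b and Klf11, and the gene model Gm12070) were chosen after their values were seen. None of these genes passed the test over all genes. With edgeR, 0 of 12675 genes had an adjusted p below 0.05, and the smallest adjusted p was 0.166, shared by 29 genes. At an unadjusted p below 0.05 there were 1245 genes, 575 higher and 670 lower with ozonated oil, where chance would give 634. DESeq2 called 241 genes, 102 higher and 139 lower. In 40.0% of tested genes both libraries of one group lay above both of the other, where chance gives 33.3%. The edgeR count was 1 without plain oil library 1 (Myc), 37 without plain oil library 2, 389 without ozonated oil library 1, and 3 without ozonated oil library 2 (Myc, Slc7a11 and Gm12070). The unadjusted count was 441, 737, 3159 and 1699 in the same order.

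**Figure D1:**
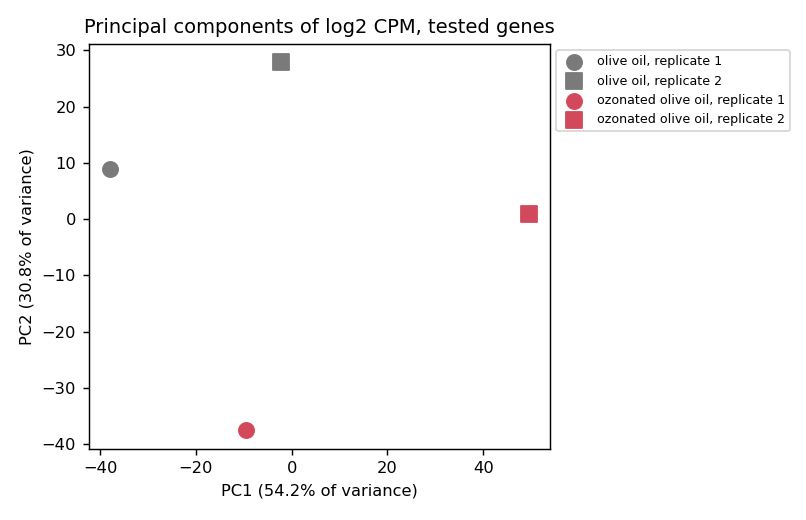
Scores of the 4 libraries on the first principal components of log2 CPM over the 12675 tested genes, with the share of variance on each axis and 1 point per library. Ozonated oil library 2 has the highest PC1 score (49.5), and plain oil library 1 the lowest (-37.98), while on PC2 both plain oil libraries (8.87 and 27.9) lie above both ozonated oil libraries (-37.58 and 0.84).

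Genes controlled by NRF2, the transcription factor of the antioxidant response, rose as a list with ozonated oil. Slc7a11 (chromosome 3, 50364936 to 50499087) went from 90.2 ± 3.80 CPM with plain oil to 356 ± 14.1 with ozonated oil (SD, n = 2 per group), a log2 change of 1.98 with a standard error of 0.18. Hmox1 (chromosome 8, 75093618 to 75100593) was at 84.2 ± 24.0 and 551 ± 232 CPM, a log2 change of 2.71 with a standard error of 0.37. Gclm, a subunit of the enzyme that limits glutathione synthesis, was at 2.33-fold, Ugdh at 1.66-fold and Srxn1, which repairs oxidised peroxiredoxins, at 2.06-fold. Nqo1, a quinone reductase, was at 18.8 ± 11.8 and 24.7 ± 11.4 CPM, a difference within the spread between libraries (edgeR adjusted p = 0.864). Of 29 tested members, 26 had a higher value with ozonated oil and 3 a lower one, with a median log2 change of 0.40. Adjusted over the list alone, 9 members passed, all higher: Slc7a11, Hmox1, Gclm, Ugdh, Gclc, Osgin1, Sqstm1, Srxn1 and Me1. Over all genes, 0 passed. Camera gave this list an adjusted p of 4.94e-10, and adjusted p = 0.685 with an estimated correlation. Its median was 0.62 without plain oil library 1, 0.097 without plain oil library 2 and 0.20 without ozonated oil library 1.

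The ferroptosis and iron list, which holds Slc7a11 and Hmox1 as well, rose with a median log2 change of 0.20. In it 17 of 22 members had higher values, and those same 2 genes were the members that passed when adjusted over the list alone, against 0 over all genes. Sat1 was at 1.39-fold and Slc3a2, the partner chain of Slc7a11, at 1.49-fold. Gpx4, which reduces lipid peroxides, was at 178 ± 27.5 CPM with plain oil and 217 ± 11.2 with ozonated oil (edgeR adjusted p = 0.722). Ptgs2 had 0 counts in all 4 libraries and was not tested. The list had an adjusted p of 0.00101 by camera, and adjusted p = 0.685 with an estimated correlation. Its median was 0.12 without ozonated oil library 2.

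Targets of ATF4, the transcription factor of the integrated stress response, also rose as a list. Atf3, a stress-induced repressor, went from 5.29 ± 2.38 to 51.2 ± 31.8 CPM, a log2 change of 3.28 with a standard error of 0.54. Ddit3, which encodes CHOP, was at 22.1 ± 8.63 and 102 ± 71.5 CPM (4.63-fold), and Ppp1r15a at 2.30-fold. Chac1, which degrades glutathione, varied more within groups than between them, at 1.02 and 37.0 CPM in the plain oil libraries and 13.0 and 87.0 in the ozonated oil libraries (edgeR adjusted p = 0.814). Of 27 tested members, 25 had higher values, with a median log2 change of 0.66. Both ozonated oil libraries lay above both plain oil libraries for 8 of them. Adjusted over the list alone, 4 members passed, all higher (Slc7a11, Atf3, Ppp1r15a and Ddit3), and 0 passed over all genes. List medians relative to the plain oil mean were -0.47 and 0.47 in plain oil libraries 1 and 2, and 0.09 and 1.34 in ozonated oil libraries 1 and 2. By camera its adjusted p was 4.52e-09, and adjusted p = 0.720 with an estimated correlation. The median of the list was 0.27 and 1.33 without plain oil libraries 1 and 2, and 1.17 and 0.011 without ozonated oil libraries 1 and 2. Without ozonated oil library 2 its adjusted p was 0.0437, and the log2 changes of Ddit3 and Atf3 were 1.21 and 2.43.

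Protein-folding genes rose in both the endoplasmic reticulum and the heat shock lists. Dnajb9, an endoplasmic reticulum co-chaperone, was at 26.1 ± 2.43 and 74.7 ± 21.6 CPM (2.86-fold), Syvn1 at 1.58-fold and Edem1 at 1.24-fold. Herpud1 was at 2.55-fold, and at 4.82-fold without plain oil library 2. Higher values were found for 20 of 20 tested members of the endoplasmic reticulum list, with a median log2 change of 0.22, and Dnajb9 alone passed when adjusted over the list alone. That list had an adjusted p of 0.00101 by camera, and adjusted p = 0.753 with an estimated correlation. In the heat shock list, Hspa1b, an inducible HSP70 gene, was at 2.17 ± 0.163 and 11.4 ± 3.68 CPM (5.23-fold), though its reads are hard to separate from those of the near-identical Hspa1a. Bag3 was at 1.78-fold, Dnajb1 at 1.67-fold and Hspa8 at 1.53-fold. Of 18 members 14 had higher values, with a median log2 change of 0.31, and Hspa1b and Bag3 passed when adjusted over the list alone. The heat shock list had an adjusted p of 0.000301 by camera, and adjusted p = 0.718 with an estimated correlation. No member of either list passed over all genes. Without ozonated oil library 2 the endoplasmic reticulum list had an adjusted p of 0.174 and a median of 0.074, and the heat shock list a median of 0.16. Without plain oil library 1 the endoplasmic reticulum median was 0.11.

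Metallothioneins, which bind zinc and other metals, rose as a list of 3 tested members, with a median log2 change of 0.88. Mt1 was at 537 ± 97.8 and 990 ± 445 CPM (1.84-fold), Mt2 at 259 ± 61.2 and 518 ± 196 CPM, and the zinc exporter Slc30a1 at 1.34-fold, each with both ozonated oil libraries above both plain oil libraries. None of the 3 passed, either adjusted over the list alone or over all genes. Camera gave them an adjusted p of 0.00868, and adjusted p = 0.700 with an estimated correlation. Without ozonated oil library 2 its adjusted p was 0.0949 and its median 0.35.

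Targets of p53 rose as a list by a median log2 change of 0.22. Trp53inp1 was at 89.9 ± 4.23 and 191 ± 26.1 CPM (2.12-fold), the cell death gene Bbc3 at 1.89-fold and Gadd45a at 1.74-fold. Sesn2 had a log2 change of 0.96, and of 1.56 without plain oil library 2. Cdkn1a, an inhibitor of cyclin-dependent kinases, was at 198 ± 72.8 and 276 ± 12.7 CPM (edgeR adjusted p = 0.665). Of 19 members 13 had higher values. Trp53inp1 passed when adjusted over the list alone, and 0 members passed over all genes. The list had an adjusted p of 0.0413 by camera, and adjusted p = 0.753 with an estimated correlation. Its adjusted p was 0.460 without plain oil library 2, 0.260 without ozonated oil library 1 and 0.0675 with no low-count filter. The median was 0.47 and 0.032 without plain oil libraries 1 and 2, 0.084 and 0.36 without ozonated oil libraries 1 and 2, and 0.13 with length and GC trends removed, a setting chosen after the data were examined.

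Genes of the BCL2 family and the caspases were not called as a list (adjusted p of 0.590 by camera), with 10 of 20 members higher and 10 lower. Bcl2, which blocks apoptosis, was at 39.3 ± 8.48 and 19.9 ± 2.71 CPM (0.507-fold), and Bid, which promotes it, at 0.628-fold. Birc2 had a log2 change of 0.37. The mitochondrial dynamics list was not called either (adjusted p of 0.724 by camera), and its smallest p belonged to Mtfp1, at 0.713-fold. In both lists 0 members passed, adjusted over the list alone or over all genes.

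Genes of glycolysis and the hypoxia response rose as a list with ozonated oil, with a median log2 change of 0.85. Hk2, which phosphorylates glucose, was at 288 ± 136 CPM with plain oil and 1218 ± 488 with ozonated oil (4.23-fold), a log2 change of 2.08 that was 2.67 without plain oil library 2. The glucose transporter Slc2a1 was at 60.4 ± 16.9 and 151 ± 17.0 CPM (2.49-fold), the collagen hydroxylase subunit P4ha1 at 2.39-fold and the phosphofructokinase gene Pfkl at 2.12-fold. Of 23 members 21 had higher values, and for 19 both ozonated oil libraries lay above both plain oil libraries. Among all 12675 tested genes 2526 did so, where chance gives 16.7% of genes in that direction. The members vary together (estimated correlation 0.41), so they are not independent draws. Adjusted over the list alone, 12 members passed, all higher: P4ha1, Slc2a1, Hk2, Pfkl, Egln3, Adm, Pdk1, Ndrg1, Bnip3, Pfkp, Slc16a3 and Pgam1. Over all genes, 0 passed. Pfkfb3, chosen after its value was seen as an exception in the list, was at 0.591-fold. List medians relative to the plain oil mean were -0.29 and 0.29 in the plain oil libraries and 0.90 and 1.03 in the ozonated oil libraries. By camera the adjusted p was 3.82e-16, and adjusted p = 0.685 with an estimated correlation.

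**Figure D2:**
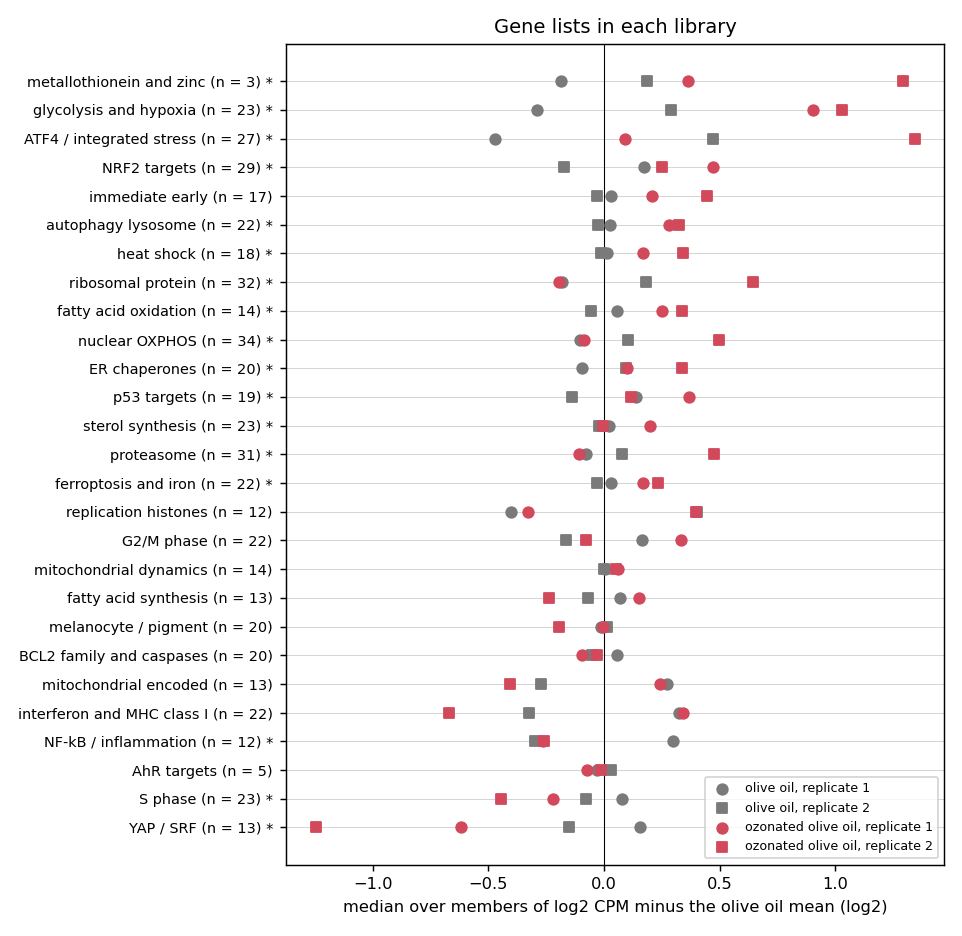
Median over the tested members of each gene list (n, number of members) of log2 CPM minus the plain oil mean, with 1 point per library, grey for plain and red for ozonated oil, and an asterisk where the camera adjusted p at the preset correlation was below 0.05. The glycolysis and hypoxia medians of the ozonated oil libraries (0.90 and 1.03) lie above those of the plain oil libraries (-0.29 and 0.29), while the ribosomal protein median of ozonated oil library 1 (-0.19) lies beside that of plain oil library 1 (-0.18).

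Autophagy and lysosome genes rose as a list, by a median log2 change of 0.32. Gabarapl1, an autophagosome protein, was at 59.5 ± 6.08 and 152 ± 0.375 CPM (2.55-fold). Gla, a lysosomal galactosidase, was at 18.0 ± 1.70 and 49.2 ± 7.24 CPM (2.74-fold), the autophagy receptor Sqstm1 at 2.21-fold and the proton pump subunit Atp6v1h at 1.47-fold. Higher values were found for 20 of 22 members, and for 16 both ozonated oil libraries lay above both plain oil libraries. Gabarapl1 and Gla passed when adjusted over the list alone, and 0 members passed over all genes. The list had an adjusted p of 9.94e-07 by camera, and adjusted p = 0.685 with an estimated correlation.

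Lipid genes were followed because both groups received an oil. Sterol synthesis genes rose as a list by a median log2 change of 0.21, with 15 of 23 higher. Insig1, a sterol-regulated brake on that pathway, was at 2.37-fold, Sqle at 1.71-fold, Mvd at 1.45-fold and Sc5d at 1.32-fold. The fatty acid oxidation list rose by a median of 0.23, with 12 of 14 higher, among them the lipid droplet gene Plin2 at 1.42-fold, Acadl at 1.35-fold and Acot2 at 1.44-fold. In both lists 0 members passed, adjusted over the list alone or over all genes. The sterol list had an adjusted p of 0.0407 by camera, and adjusted p = 0.685 with an estimated correlation. The oxidation list had an adjusted p of 0.0216 by camera, and adjusted p = 0.720 with an estimated correlation. Fatty acid synthesis genes were not called (adjusted p of 0.623 by camera), with a median of 0.04 and a mean of -0.10, of opposite sign. Within that list Elovl6, which lengthens fatty acids, was at 69.4 ± 0.659 and 20.4 ± 6.17 CPM (0.293-fold) and alone passed when adjusted over the list alone, with 0 over all genes. Me1 was at 1.56-fold. Fasn had a log2 change of -0.67, and of -1.41 without ozonated oil library 1. Pdk4 had counts of 2, 0, 0 and 2 and was not tested. The sterol list had an adjusted p of 0.0897, 0.0967 and 0.303 without plain oil library 1, plain oil library 2 and ozonated oil library 1, and its median was -0.037 without the last of these. The oxidation list had 0.670, 0.0808 and 0.158 without plain oil library 2, ozonated oil library 1 and ozonated oil library 2, and 0.0740 with no filter, while the synthesis list passed without ozonated oil library 1 (0.0268, lower). The oxidation median was 0.51 and 0.056 without plain oil libraries 1 and 2. The synthesis median was 0.090 and -0.091 without plain oil libraries 1 and 2, and -0.27 and 0.14 without ozonated oil libraries 1 and 2.

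Genes of DNA replication and S phase fell as a list with ozonated oil. All 23 tested members had lower values, with a median log2 change of -0.32, and for 13 the groups did not overlap. Ung, which removes uracil from DNA, was at 17.7 ± 0.632 and 5.83 ± 1.43 CPM (0.331-fold). Cdc6, which loads the replicative helicase, was at 69.0 ± 5.39 and 33.4 ± 4.32 CPM (0.484-fold), Ccne1 at 0.577-fold and Uhrf1 at 0.555-fold. Ung and Cdc6 passed when adjusted over the list alone, and 0 members passed over all genes. Camera gave an adjusted p of 3.64e-07 for S phase, and adjusted p = 0.718 with an estimated correlation. Without ozonated oil library 1 its median was -0.49. The G2 and M phase list was not called (adjusted p of 0.194 by camera), with log2 changes of 0.38 for Nusap1 and 0.32 for Ccnb1. That list passed, higher, without plain oil library 1 (0.00159) and without ozonated oil library 2 (0.000443), and had the opposite direction without plain oil library 2 (0.730) or ozonated oil library 1 (0.494).

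Immediate-early genes moved both ways. Myc (chromosome 15, 61985341 to 61990361) was at 82.7 ± 1.66 CPM with plain oil and 12.6 ± 4.47 with ozonated oil, a log2 change of -2.71 with a standard error of 0.28. Dusp6 was at 50.1 ± 17.9 and 7.90 ± 2.04 CPM. In the other direction, Jun was at 37.7 ± 11.3 and 150 ± 14.6 CPM, and Dusp1, a phosphatase of stress kinases, at 2.70-fold. Adjusted over the list alone, 5 members passed as higher (Jun, Dusp1, Atf3, Klf4 and Jund) and 3 as lower (Myc, Dusp6 and Nr4a1), and 0 passed over all genes. As a list of 17 they were not called (adjusted p of 0.350 by camera). The list passed, higher, without plain oil library 1 (0.0436) and without ozonated oil library 1 (0.0294), and had the opposite direction without ozonated oil library 2 (0.846).

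Target genes of YAP and SRF, which respond to the cytoskeleton and cell contact, fell as a list by a median log2 change of -0.73. Ajuba was at 66.9 ± 2.73 and 21.9 ± 0.947 CPM (0.327-fold), Ccn1 at 0.314-fold, Lats2, a kinase that restrains YAP, at 0.497-fold and Amotl2 at 0.605-fold. Of 13 tested members 11 had lower values, and 6 passed as lower when adjusted over the list alone (Ajuba, Ccn1, Amotl2, Lats2, F3 and Ccn2). Over all genes, 0 passed. List medians were 0.15 and -0.15 in the plain oil libraries and -0.62 and -1.25 in the ozonated oil libraries. Camera gave YAP and SRF targets an adjusted p of 4.67e-08, and adjusted p = 0.685 with an estimated correlation. Their median was -1.29 without ozonated oil library 1.

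Inflammatory genes of the NF-kB list fell with a median log2 change of -0.16. The chemokine gene Cxcl1 was at 3.53 ± 2.32 and 0.370 ± 0.221 CPM, Csf1, a macrophage growth factor gene, at 30.4 ± 16.2 and 11.3 ± 0.985, and Tnfaip3 at 0.359-fold. Log2 changes of Cxcl1, Csf1 and Cxcl10 were -3.26, -1.42 and -2.33, against -2.36, -0.74 and -1.18 without plain oil library 1, and Cxcl1 had -4.05 without ozonated oil library 1 and Cxcl10 -2.96 without plain oil library 2. Of 12 tested members 7 had lower values, and 0 passed, adjusted over the list alone or over all genes. The list had an adjusted p of 0.0191 by camera, and adjusted p = 0.767 with an estimated correlation. It had 0.327 without plain oil library 1 and 0.325 without ozonated oil library 1. Its median was 0.0085 and -0.61 without plain oil libraries 1 and 2, and -0.40 and -0.32 without ozonated oil libraries 1 and 2. Interferon and MHC class I genes were not called (adjusted p of 0.929 by camera). Rsad2 was at 1.91-fold and Ifit2 at 0.700-fold, and 0 members passed when adjusted over the list alone. The median of that list was -0.07, with the camera direction opposite in sign, and library medians were 0.32 and -0.32 with plain oil and 0.34 and -0.67 with ozonated oil. It passed as higher without plain oil library 1 (0.0192) and as lower without plain oil library 2 (0.00568). The list of targets of the aryl hydrocarbon receptor was not called (adjusted p of 0.724 by camera, 5 tested members), with Tiparp at 1.32-fold and Cyp1a1 at 0.310-fold, or 0.492-fold without ozonated oil library 1 and 0.0993-fold without ozonated oil library 2.

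Among pigment cell genes, Mitf, the master transcription factor of melanocytes, was at 653 ± 55.3 CPM with plain oil and 304 ± 71.5 with ozonated oil, a log2 change of -1.10 with a standard error of 0.24. Mc1r, the melanocortin receptor, was at 535 ± 3.19 and 265 ± 23.6 CPM (0.496-fold), and the growth factor receptor Kit at 0.469-fold. Tyr, the enzyme that starts melanin synthesis, was at 534 ± 56.1 and 533 ± 134 CPM (edgeR adjusted p = 0.999). Dct, Tyrp1 and Pmel, named after their values were seen as the other pigment genes of the list, had log2 changes of 0.20, -0.04 and 0.37, each below its standard error. Rab27a, which moves pigment granules, was at 1.42-fold. Of 20 tested members 9 had higher and 11 lower values. Mc1r and Mitf passed as lower when adjusted over the list alone, and 0 members passed over all genes. The list was not called (adjusted p of 0.170 by camera), and passed, lower, without ozonated oil library 1 (0.0306).

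**Figure D3:**
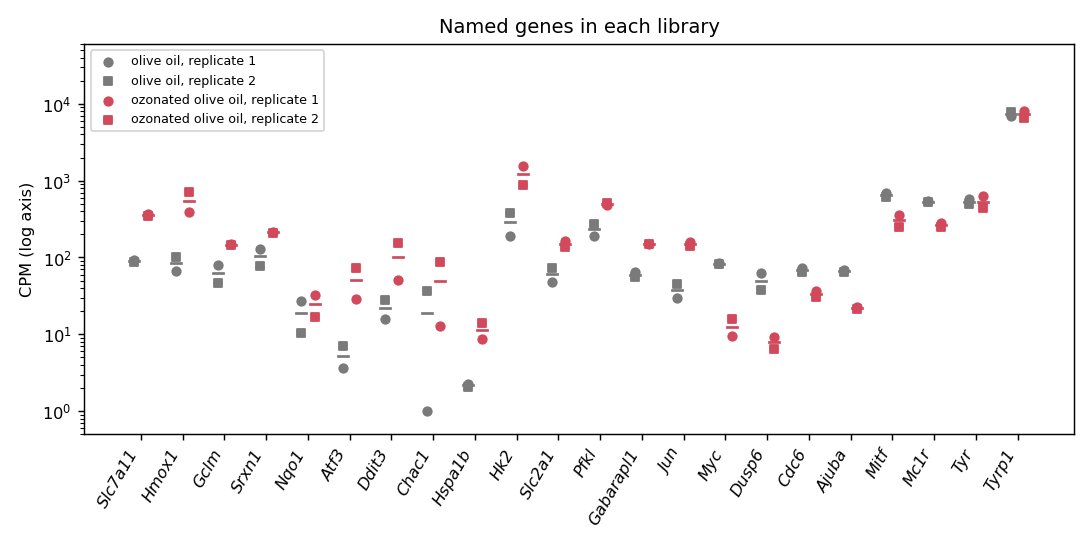
CPM of 22 genes in each library on a log axis, with 1 point per library, grey for plain and red for ozonated oil, and a bar at each group mean. Slc7a11 lies at 87.5 and 92.9 CPM with plain oil and 346 and 366 with ozonated oil, Myc at 81.5 and 83.9 against 9.47 and 15.8, and the Tyr and Tyrp1 points of the groups overlap.

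Ribosomal protein, proteasome and nuclear respiratory chain genes rose as lists, and the direction turned without ozonated oil library 2. Higher values were found for 32 of 32 ribosomal protein genes, 31 of 31 proteasome genes and 33 of 34 respiratory chain genes, with median log2 changes of 0.27, 0.20 and 0.22. Psmd14 was at 1.26-fold and Ndufa1 at 1.35-fold, and 0 members of these lists passed, adjusted over the list alone or over all genes. In ozonated oil library 2 the medians were 0.64, 0.47 and 0.50, while in ozonated oil library 1 they were -0.19, -0.11 and -0.08. That library also had the most counts, the highest share of the ribosomal RNA precursor Rn45s (1.10%, against 0.383% in ozonated oil library 1 and 0.249% and 0.386% with plain oil) and the highest PC1 score. Its difference from ozonated oil library 1 followed transcript length across genes, which are not independent replicates (Spearman -0.457), and the members of the 3 lists have a median length of 1445 nt against 3341 nt for all tested genes. Camera gave adjusted p of 0.0204 for ribosomal proteins, 0.0238 for the proteasome and 0.0120 for the respiratory chain, and each had adjusted p = 0.823 with an estimated correlation. Without ozonated oil library 2 all 3 lists had the opposite direction, with adjusted p of 0.0129, 0.118 and 0.248 and medians of -0.21, -0.12 and -0.10, against 0.61, 0.44 and 0.45 without ozonated oil library 1. Without plain oil library 1 they had 0.653, 0.239 and 0.153. The ribosomal protein median was 0.11 and 0.47 without plain oil libraries 1 and 2, and 0.18 with length and GC trends removed, a setting chosen after the data were examined.

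Genes encoded in mitochondrial DNA were not called as a list (adjusted p of 0.851 by camera). They held 2.66% and 1.85% of the counts of the plain oil libraries and 2.82% and 1.69% of those of the ozonated oil libraries. Replication-dependent histone genes were not called (adjusted p of 0.724 by camera, 12 tested members), with H1f2 at 1.16-fold. In these 2 lists 0 members passed, adjusted over the list alone or over all genes.

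Markers of other cell types were low, and their sums overlapped between the groups except for the few erythroid counts (0 and 1 with plain oil, 5 and 4 with ozonated oil). The keratin genes Krt1, Krt5, Krt10 and Krt14 together were at 25.5 and 3.51 CPM in plain oil libraries 1 and 2 and 0.922 and 17.8 in ozonated oil libraries 1 and 2. The keratinocyte list was not called (adjusted p of 0.380 by camera), and passed as lower without plain oil library 2 (0.00568) and without ozonated oil library 2 (0.000849), with the opposite direction when either of the other libraries was left out (0.0901 and 0.141). Fibroblast markers summed to 32.3, 15.0, 28.6 and 11.99 CPM in the same order and were not called (adjusted p of 0.431 by camera). Immune markers summed to 2.53, 0.471, 2.99 and 0.466 CPM, endothelial markers to 2.62, 3.81, 3.65 and 2.997 CPM, and erythroid markers to at most 0.220 CPM, with too few tested members for a list test. Col1a2, Krt14, Lyz2 and Vwf had the smallest p in their lists, at 0.791-fold, 0.454-fold, 1.26-fold and 1.10-fold, each with p of at least 0.363. With a library left out, Krt14 ranged from 0.0658-fold to 2.17-fold and Lyz2 from 0.273-fold to 4.27-fold.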

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

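Of the settings below, the fit with length and GC trends removed and the fit without Rn45s were chosen after the data were examined, and the others before. The count of genes with edgeR adjusted p below 0.05 was 0, and stayed 0 with median-of-ratios scaling, the stricter filter, both stricter thresholds, the test against a fold of 1.5 and both later fits. It was 4 with no filter (Slc7a11 higher; Myc, Cdca7 and Spsb4 lower), 241 with DESeq2 and 1 to 389 with a library left out. The labels do not say that a replicate number marks a shared culture, and with 2 pairs the data cannot settle it. The replicate differences of both groups correlated at 0.446 across genes, which are not independent. With the replicate number as a block, 1160 genes were called (490 higher, 670 lower), among them all 241 DESeq2 calls. The count at an unadjusted p below 0.05 was 1245, with 2632 under the block and 441 to 3159 with a library left out. The cause of these shifts was not tested. Simulated calls of DESeq2 and of the block were false in 19.7% and 21.1%, against 9.7% for the group-only edgeR fit. The simulated counts held no replicate effect, so these shares cannot say how many of the block's calls on the real data are false.

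Camera called 17 of 29 lists at the preset correlation. It called 0 with an estimated correlation (smallest adjusted p 0.685, and 0 lists at an unadjusted p below 0.05). Fry called 0 (smallest adjusted p 0.373, 2 lists at an unadjusted p below 0.05). For ferroptosis and iron and for sterol synthesis the estimate was below the preset. Their unadjusted camera p still rose, from 0.000296 to 0.0589 and from 0.0224 to 0.142. Correlation between genes therefore does not account for the loss of those calls, and what does was not tested. All 17 kept their call and direction under the block, which also called immediate-early genes (0.0452) and moved the later ribosome assembly list to an estimated-correlation p of 0.0601. With each library left out in turn, 8 of the 17 kept their call in all 4 fits. Directions turned for the interferon list with the stricter filter (adjusted p 0.914) and the block (0.840), and for the aryl hydrocarbon receptor list with the stricter filter (0.554). With a library left out, directions turned in at least 1 fit of 12 lists. Their adjusted p ranged 0.000443 to 0.730 for G2 and M phase, 0.0268 to 0.653 for fatty acid synthesis, 1.09e-08 to 0.248 for the nuclear respiratory chain and 0.0949 to 0.327 for mitochondrial-encoded genes. They ranged 7.45e-11 to 0.653 for ribosomal proteins, 9.42e-08 to 0.239 for the proteasome, 0.0294 to 0.846 for immediate-early genes and 0.00568 to 0.121 for interferon genes. They ranged 0.670 to 0.962 for aryl hydrocarbon receptor targets, 0.0861 to 0.847 for fibroblast, 0.000849 to 0.141 for keratinocyte and 0.0681 to 0.298 for histone genes. Of 1077 gene results over 98 genes followed, 9 turned sign, each with a library left out. Log2 changes then ranged -0.20 to 1.24 for Nqo1, -0.55 to 5.62 for Chac1, -0.32 to 0.22 for Tyr, -0.067 to 0.42 for Dct, -0.21 to 0.085 for Tyrp1 and -0.013 to 0.77 for Pmel. Depth was at least 22539486 counts in each library. At these depths, the fitted spread and 2 libraries per group, 22.2% of simulated 2-fold changes were recovered, and which of these set the limit was not tested. Recovery in the real data may differ, because the simulated spread was equal in both groups and held no replicate effect.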

Other observations

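The 3 tests of whether a single ozonated oil library carries a pattern, and the choice of the 2 gene lists used here, came after the results were seen. Ribosome assembly genes, which encode the nucleolar machinery that builds ribosomes, were lower with ozonated oil. Ppan, Dkc1 and Grwd1 were noticed among the smallest p-values, and a list of 46 other genes of this process was then written. Of these, 44 had lower values, 40 with both ozonated oil libraries below both plain oil libraries, and the exceptions were Polr1c and Npm1. Rrp1b had a log2 change of -1.49, Nop2 -1.19, Rrp12 -1.14 and the RNA polymerase I subunit gene Polr1b -1.65. Adjusted over the list alone 26 genes passed, all lower, and 0 passed over all genes. Library medians were -0.02 and 0.02 with plain oil and -0.59 and -0.64 with ozonated oil. With all 4 libraries and no block, this list passed with an estimated correlation, at p = 0.00686, or 0.0137 adjusted over the 2 later lists, and by fry at an adjusted 0.00427. The process was picked because Ppan, Dkc1 and Grwd1 stood out in these same libraries, so these p-values are not independent of that choice. Nor does the adjustment cover other processes that could have been picked. The estimated-correlation p was 0.0483 without plain oil library 1, 0.0671 without plain oil library 2, 0.0696 without ozonated oil library 1 and 0.0572 without ozonated oil library 2, while the median was -0.62, -0.58, -0.67 and -0.60.

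Genes that ERK signalling of the MAPK pathway switches on, among them the feedback inhibitors of the Dusp, Spry and Spred families, were also mostly lower. Of 16 tested genes 12 had lower values, 11 of them passing when adjusted over the list alone, with 0 over all genes and a median log2 change of -1.39. The values of all its tested genes had been seen before the list was written, so neither these counts nor the p-values below are independent evidence of the direction. Dusp6 was at -2.67. Ccnd1 was at -2.43, and at -1.77 without plain oil library 1 and -3.44 without ozonated oil library 1. Etv5 was at -4.28 and Spry4 at -3.23, with -2.78 and -1.62 without plain oil library 1, -4.99 and -3.97 without plain oil library 2, and -5.68 and -4.01 without ozonated oil library 1, and Etv5 had -3.54 without ozonated oil library 2. Spred2 was at -1.65, Spry2 at -1.83, Spry1 at -1.54 and Dusp4 at -1.28, while Phlda1 at 0.66 and Ier3 at 1.29 (1.996 without plain oil library 2 and 0.40 without ozonated oil library 2) went the other way. The list had camera p = 8.28e-14 at the preset correlation and p = 0.0754 with an estimated correlation.

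For the glycolysis and hypoxia list, length and GC bias predicts that the change shrinks once each library's trend is removed, and the median went from 0.85 to 0.893, which argues against it. The nearer ozonated oil library stood at 0.903 and the higher plain oil library at 0.289, which argues against a single library as the source. Removing the slope of change on replicate difference across genes left a median of 0.765 out of 0.87 on the log2 CPM scale. At that slope (0.265), the axis that separates libraries of a group accounts for little of the change. The slope is an average over all genes, and a list that follows the axis more steeply would not be fully adjusted, so the axis is not excluded. For the ATF4 list the same adjustment left 0.396 out of 0.64, with members spread by 0.24, so it cannot separate the oil from that axis. Each oil has a library of each number, so a replicate difference equal in both oils would cancel in the change, while an unequal difference would not. The ATF4 median of ozonated oil library 1 (0.089) lay below that of plain oil library 2 (0.469) and above that of plain oil library 1 (-0.469). The rise of that median may therefore come from ozonated oil library 2 alone. A response of glucose and hypoxia genes to ozonated oil is a hypothesis, and differences in cell density, medium or oxygen between dishes were not tested and stay open.

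Members of the ribosomal protein, proteasome and nuclear respiratory chain lists have short transcripts, with a median of 1445 nt against 3341 nt for all tested genes, and the difference between the ozonated oil libraries followed length across genes (Spearman -0.457). Removing length and GC trends left a median of 0.173 out of 0.24, which argues against that bias as the whole source. The lower ozonated oil library had a median of -0.122, and the plain oil libraries reached up to 0.122. The rise of these lists may therefore come from ozonated oil library 2 alone. Whether that library differs in RNA quality, handling or culture was not tested.

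For the list of MAPK genes, removing length and GC trends left a median of -1.391 against -1.387 before, which argues against a length bias as the source. The nearer ozonated oil library stood at -1.011 and the lower plain oil library at -0.199, but the genes were chosen after they were seen to differ, so a single library as the source cannot be judged from them. For ribosome assembly, the list written without the genes first noticed had a median of -0.61 with 95.7% of members lower, as lower expression of the class predicts. That prediction restates the pattern for other genes of the process in the same libraries, so it tests no cause. Culture differences between the groups other than the oil stay open.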
